A study of Mus musculus with 6 samples.

How the data were processed

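Messenger RNA was measured in mouse embryonic stem (ES) cells with Affymetrix expression arrays, on which a transcript is read by a probe set, a group of short probes. The labels describe total RNA, amplified into biotin-labelled cRNA by in vitro transcription. They give 2 groups of 3 arrays, each group being 1 cell line in the undifferentiated state. The heterozygous line, D4, keeps 1 intact copy of Dicer, and the null line has none; the sample titles call the null line 27H and the series title 27H10. Every array was placed in its group from its title. The labels do not say whether the 3 arrays of a line came from separate cultures, so p-values measure only the spread between these samples, which may be technical. With 1 line per genotype, genotype and line cannot be told apart. The labels give the same day of analysis for all arrays, and no other batch is known.

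The deposited values are intensities on a linear scale, per the values themselves, with 1 value for each of 45101 probe sets. The mean of every array after trimming 2% at each end was 500 units, while the lower and upper quantiles differed between arrays. GCRMA is the only tool named in the submitters' processing notes; the deposited intensities are not on its log2 scale and are not quantile normalized, so the step in which it was used is unknown. Global scaling to a fixed trimmed mean leaves differences in the shape of the distribution between arrays in place. The median intensity was between 49.1 and 52.7 in the heterozygous arrays and between 44.9 and 46.5 in the null arrays. No detection calls were used here, so low intensities could not be sorted into signal and background. Intensity is in arbitrary units, and the number of arrays limits the precision.

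The 64 control probe sets were left out of the tests. Of the other probe sets, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 none; 0 symbols changed when updated through the mouse gene table of assembly GRCm38.p6. Values were turned into log2. Probe sets had to reach a log2 value of 5, an intensity of 32, in at least 3 of the 6 arrays. Each gene was represented by the probe set with the highest mean over the 6 arrays, among those with a single symbol, which left 12927 genes. The design had been written for log2 values and provided for this transformation.

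Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05 and a log2 difference of at least 1, a 2-fold change, in either direction. Differences are null minus heterozygous throughout. Means ± SD are of the linear intensities of 3 arrays, and fold changes come from the means of log2 values. For some genes with a group near the floor, a fold with values under 32 raised to 32 is given too. A test used simulated data with the same 12927 genes and 6 arrays. Of the 50 genes changed by a log2 of 0.75, 2% were called, and 78% of those changed by 1.5. Of those changed by 2.5 and 4, 84% and 92% were called, along with 11 of 12727 unchanged genes. A change of 0.75 lies under the threshold of size, so few calls were fixed in advance there. Noise was normal, with a spread typical of genes of like intensity, so genes of unusually wide spread are not covered.

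The 23 gene lists were fixed before the data were examined and hold 436 symbols, of which 2 (Dux and Rigi) had no match in the annotation. They were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01 and with an intensity trend, adjusted over the 23 lists. Camera with a correlation estimated for each list, and fry, which tests whether a list's genes move one way on balance, were run beside it. On simulated data with 20 lists, camera found the 1 list shifted by a log2 of 1 and called 0 of the others. Genes were simulated independently, so this could not show false calls that come from correlation between genes.

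The genes named are Dicer1, 12 genes chosen whatever their values, the 10 largest increases and 10 largest decreases among called genes whose arrays did not overlap, and up to 4 called members of each list by size of change. Where a list had fewer than 2 called members, up to 2 with the largest change at an adjusted p under 0.05 are named. A gene outside this rule is named only as an example and was picked after its values were seen. Chromosome names and the order of neighbouring genes come from the mouse gene table of assembly GRCm38.p6.

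The alternatives were other filters on low values, other variance priors, the replicate number as a block, further normalization, other ways to combine probe sets, array weights, other thresholds and leaving out each array. Those added after seeing the data were other log scales, centring on the tested genes and leaving out the genes of chromosomes 1 and 11. The setting without probe sets that share sequence dropped those ending in _s_at, _x_at or _a_at. The _a_at ending marks probe sets that read several transcripts of 1 gene, so a value lost with them is no sign that another gene was read. A test of microRNA seed matches in 3′ untranslated regions had been planned; sequences of these regions were not used here, and the test was not run.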

Results

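The series compared undifferentiated mouse ES cells with and without Dicer, the ribonuclease that cuts microRNA precursors into mature microRNAs. The comparison asks which transcripts differ when Dicer is missing. Expression was measured on 3 arrays of a Dicer +/- line and 3 arrays of a Dicer -/- line, called heterozygous and null cells here. Between 56.9% and 60.3% of the probe sets of an array reached an intensity of 32. Pearson correlations across the tested genes, which are not independent replicates, were 0.967 to 0.973 within a line and 0.924 to 0.928 between lines. The first principal component held 57.6% of the variance and separated the lines.

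Dicer1 transcript was not lower in the null cells. Its brighter probe set, 1427941_at, read 1098 ± 39.2 in heterozygous and 1197 ± 62.2 in null cells (SD, n = 3), a log2 difference of 0.12 with a limma adjusted p of 0.264 over all probe sets. The other, 1460571_at, read 370 ± 32.5 and 368 ± 34.0, with an adjusted p of 0.962. The labels do not say which part of the gene was deleted, so a probe set outside that part checks nothing about the genotype.

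Null cells differed from heterozygous cells at many genes, in both directions. Of 12927 genes tested, 934 were called higher and 802 lower in null cells, 1736 in all. At an adjusted p under 0.05 with no limit on size, 3162 genes were higher and 3143 lower. The arrays of the lines did not overlap for 1726 of the called genes, and for 57.2% of all tested genes, against 10% by chance for 3 arrays against 3. Centring each array on the median of all its probe sets moved the median of the tested genes from -0.01 to 0.14 and the split of the calls to 1268 higher and 574 lower. The balance between the directions therefore depends on the scaling.

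The largest increases included genes barely detected in heterozygous cells. Zbp1, a sensor of left-handed nucleic acids that is induced by interferon, rose from 59.5 ± 2.29 to 1298 ± 82.4 (SD, n = 3), a fold of 21.8. Msln, which encodes the cell-surface protein mesothelin, rose from 48.1 ± 24.6 to 969 ± 48.6, and C1qtnf9, which encodes a secreted relative of complement C1q, rose from 32.5 ± 4.30 to 701 ± 36.8. Gm364, a gene on the X chromosome, rose from 150 ± 24.1 to 3176 ± 720. Lgals3bp, which encodes a secreted galectin-binding glycoprotein, rose from 17.0 ± 20.5 to 467 ± 89.2, a fold of 45.2, or 13.3 with values under 32 raised to 32. With the same floor, the folds were 6.78 for Lpo (lactoperoxidase), 6.46 for Lrrn2, 3.53 for Gcnt3, 3.22 for Akr1c13 and 1.38 for Atp2c2, all of them under 32 in every heterozygous array. Atp2c2 lost its call with the floor, at a log2 difference of 0.46, with the replicate number as a block (limma adjusted p 0.0515) and with robust eBayes (0.0504).

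Among the largest decreases, Spink1, a secreted inhibitor of trypsin, fell from 2990 ± 307 to 87.5 ± 11.8 (SD, n = 3), 34.2-fold lower. Slc39a8, a transporter of zinc and other metals, fell from 374 ± 67.1 to 11.9 ± 10.5, 43.6-fold lower, or 11.6-fold with values under 32 raised to 32. Tmem54 was 8.89-fold lower on that scale, Trpm1 (a cation channel) 5.40-fold, Crabp1 (a cytoplasmic carrier of retinoic acid) 5.26-fold, Calb2 (the calcium-binding protein calretinin) 4.10-fold and Zfp873 2.36-fold. The transcripts 1700108F19Rik, 1700019A02Rik and 1700012D14Rik were 4.54-fold, 2.11-fold and 1.91-fold lower. The last was no longer called with the floor, at -0.93, and Crabp1 was not called with eBayes without an intensity trend (adjusted p 0.0853). Zfp873 was not called without heterozygous replicate 1, 2 or 3, at log2 differences of -3.80, -3.91 and -3.71 and adjusted p values of 0.0565, 0.0531 and 0.0608.

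Published targets of the miR-290 family, abundant microRNAs of ES cells, were higher in null cells. Of 17 measured, 6 rose past both thresholds, 1 fell, and 13 were higher and 1 lower at the adjusted p alone. Rbl2, a relative of the retinoblastoma protein that represses E2F targets, rose from 133 ± 36.0 to 551 ± 80.3 (SD, n = 3), a log2 difference of 2.08 ± 0.20 (SE) with a limma adjusted p of 8.93e-06. Lats2, a kinase of the Hippo pathway, rose by 1.92, the cyclin-dependent kinase inhibitor Cdkn1a (p21) by 1.60, the initiator caspase Casp2 by 1.57 and the chromatin remodelling subunit Smarcc2 by 1.48. Irf2, an interferon regulatory factor, rose from 28.5 ± 14.4 to 101 ± 26.3, a fold of 2.83 with values under 32 raised to 32. Dkk1, an inhibitor of Wnt signalling, fell, at a log2 difference of -1.59, or 2.60-fold with the same floor. The list's median was 0.81 and its camera adjusted p 0.000156; the adjusted p was 0.116 with an estimated correlation. For this list and all others, the counts of called genes were the same when adjusted over the list alone.

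The Nodal inhibitors of this list did not reach the 2-fold threshold. Lefty2 read 1492 ± 41.2 and 2549 ± 262 (SD, n = 3), a fold of 1.70 with a limma adjusted p of 1.91e-05. Lefty1 read 6544 ± 158 and 7733 ± 157, a log2 difference of 0.24 with an adjusted p of 0.00442. Both lie on chromosome 1, whose tested genes had a median log2 difference of 0.31.

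**Figure D1:**
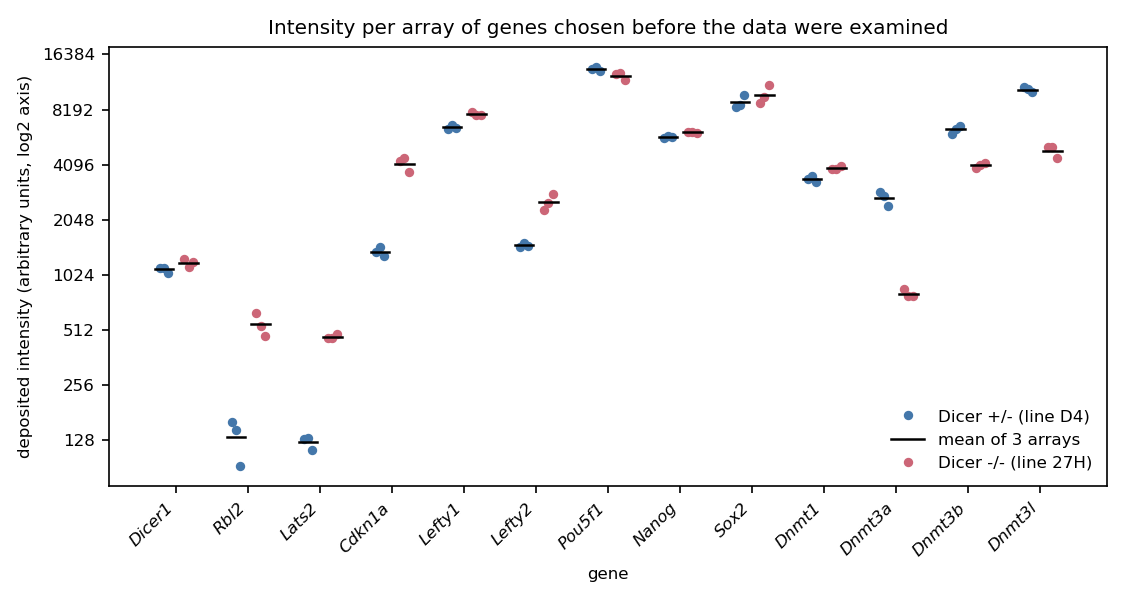
Deposited intensity on a log2 axis (arbitrary units) of 13 genes chosen before the data were examined, with blue points for the 3 heterozygous arrays, red points for the 3 null arrays and black bars for their means. Rbl2, Lats2 and Cdkn1a sit higher and Dnmt3a and Dnmt3l lower in every null array, while the Pou5f1 means are 13643 and 12509.

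Of 15 inhibitors of the passage from G1 into S phase, 6 were called higher and 0 lower. Beside Rbl2, Lats2 and Cdkn1a these were the Hippo kinase Lats1 (log2 difference 1.36), Cdkn2a (1.13), which encodes p16 and ARF, and the antiproliferative factor Btg2 (1.01). Btg2 is on chromosome 1. The median was 0.67 and the camera adjusted p 0.0139, against an adjusted p of 0.26 with an estimated correlation. The camera adjusted p was 0.0553 with a log2 filter of 7 and 0.0706 without probe sets that share sequence, and Lats1 was 0.76 as a mean over its probe sets. The setting without shared sequence leaves out Rbl2, whose probe sets end in _a_at and were at 1.53 and 2.08. Of the 20 genes measured on the proliferation list, 0 were called, against 5 higher and 5 lower at the adjusted p alone. The list was not called (camera adjusted p 0.919). The cyclin Ccne2 differed by 0.88 and Ccne1, also a cyclin of the G1 to S transition, by -0.72. Ccne2 was called with arrays centred on their medians (1.03), without heterozygous replicate 3 (1.01) and without null replicate 1 (1.01).

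Pluripotency genes did not pass the test of a shift as a group (camera adjusted p 0.622). Pou5f1 (Oct4) read 13643 ± 381 and 12509 ± 612, Nanog 5813 ± 69.0 and 6146 ± 36.7, and Sox2 8992 ± 765 and 9854 ± 1124 (SD, n = 3), with limma adjusted p values of 0.104, 0.263 and 0.252. The sign of the Pou5f1 difference, -0.13, turned to 0.03 when arrays were centred on their medians. Of 26 genes measured, 1 was called higher and 3 lower. Lin28a, which encodes an RNA-binding protein that blocks let-7 maturation, fell from 5094 ± 292 to 864 ± 86.5, 5.91-fold lower with an adjusted p of 5.48e-09. Dppa3 (Stella) fell 2.89-fold and Dppa4 2.01-fold, and Prdm14, a repressor that sustains naive pluripotency and lies on chromosome 1, rose 2.96-fold. Dppa4 was short of the threshold without null replicate 3 (-0.97), with arrays centred on their medians (-0.86) and with array weights (-0.99).

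Transcripts of Dnmt3a and Dnmt3l, which act in de novo DNA methylation, were lower in null cells. Dnmt3a, a de novo methyltransferase, fell from 2690 ± 230 to 811 ± 42.1 (SD, n = 3), 3.31-fold lower with a limma adjusted p of 6.16e-08. Dnmt3l, the cofactor of Dnmt3a and Dnmt3b, fell from 10527 ± 303 to 4868 ± 377, 2.17-fold lower. Dnmt3b differed by -0.65 with its brighter probe set and by -0.97 with the other, below the threshold of size, at adjusted p values of 9.89e-06 over genes and 2.2e-05 over probe sets. Dnmt1, the maintenance methyltransferase, differed by 0.20 with an adjusted p of 0.02. The Dnmt3a probe sets disagreed: 1423064_at, 1423065_at and 1423066_at were at -1.73, -1.54 and -1.56, 1423063_at at 0.28 and 1460324_at at 0.81, and their mean was -0.75. Dnmt3l was at -0.96 with arrays centred on their medians. Among other members, the DNA glycosylase Mbd4 fell (-1.48) and the methyl-CpG binding protein Mbd1 was called higher (1.34). Mbd1 was at 0.15 without probe sets that share sequence, a setting that replaces its _a_at probe set by another. As means over probe sets, Mbd1 was at 0.87 and Mbd4 at -0.95. The whole list, 17 measured with 1 higher and 3 lower, was not called (camera adjusted p 0.0734), but was called lower with the replicate number as a block (0.0415).

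Imprinted genes, which are expressed from 1 parental copy, were lower in null cells. Of 24 measured, 10 fell, 1 rose, and 16 were lower and 2 higher at the adjusted p alone. Nnat, which encodes the membrane proteolipid neuronatin, fell from 3149 ± 71.4 to 533 ± 50.9 (SD, n = 3), 5.93-fold lower. Rian, a maternally expressed non-coding RNA, fell 5.11-fold, the growth factor Igf2 4.43-fold and Magel2 3.85-fold. Meg3, the non-coding RNA beside Rian, fell as well (-1.82), and so did Dlk1 (-1.64), the paternally expressed gene of the same domain. The 1 member called higher was Plagl1, a zinc finger factor, at 1.11. Mest read 6040 ± 138 and 6408 ± 459. The list's median was -0.99 and its camera adjusted p 1.88e-05; the adjusted p was 0.116 with an estimated correlation.

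Genes induced by interferon or double-stranded RNA were higher. Of 13 measured, 7 were called higher and 1 lower, and 10 were higher and 1 lower at the adjusted p alone. Oas1a, which makes the activator of RNase L, rose from 620 ± 35.4 to 2288 ± 147 (SD, n = 3), 3.69-fold with a limma adjusted p of 3.17e-08. Irf9, the DNA-binding part of the ISGF3 complex, rose 3.90-fold. Ifit1, an inhibitor of viral RNA translation, rose from 11.9 ± 14.3 to 113 ± 6.5, which is 3.51-fold with values under 32 raised to 32. Ifih1 (MDA5), a sensor of long double-stranded RNA, was 3.81-fold higher, or 2.27-fold with values under 32 raised to 32. It was not called without heterozygous replicate 2 (log2 difference 1.21), null replicate 1 (1.62) or null replicate 3 (1.83), or with eBayes without an intensity trend (adjusted p 0.0882). The gene that fell was Bst2 (-1.10), which encodes tetherin. The median was 1.19 and the camera adjusted p 0.0139, against an adjusted p of 0.266 with an estimated correlation. The median was 0.76 with no filter, with a log2 filter of 7 and without probe sets that share sequence, and the camera adjusted p was 0.0589 and 0.142 in the last 2.

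Of 16 primitive endoderm markers measured, 6 were called lower and 1 higher, and 8 were lower and 2 higher at the adjusted p alone. Gata4 and Pdgfra, both of low intensity, differed by -0.09 and -0.23 (limma adjusted p 0.87 and 0.727). Dab2, an endocytic adaptor, fell from 683 ± 125 to 155 ± 20.9 (SD, n = 3), 4.39-fold lower. Cubn, the receptor cubilin, fell 3.71-fold, the laminin subunit Lama1 by 1.76 on the log2 scale and the transcription factor Gata6 from 108 ± 21.6 to 38.3 ± 21.6, 2.66-fold with values under 32 raised to 32. Sparc, a matrix glycoprotein, rose from 6091 ± 442 to 12295 ± 840. The list's median was -1.10 and its camera adjusted p 0.0145, against an adjusted p of 0.31 with an estimated correlation. The median was -0.73 without null replicate 1 and -0.71 with values under 32 raised to 32, and the list stayed called in both. The camera adjusted p was 0.0553 with a log2 filter of 7 and 0.0706 without probe sets that share sequence.

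Glycolysis genes were lower by small amounts. Of 16 measured, 0 were called, 10 were lower and 1 higher at the adjusted p alone. Pfkl, the liver-type phosphofructokinase subunit, read 5440 ± 444 and 3089 ± 102 (SD, n = 3), a log2 difference of -0.81. Pgk1, phosphoglycerate kinase, differed by -0.69 and is on the X chromosome, whose tested genes had a median of -0.15. The list's median was -0.36 and its camera adjusted p 0.0139, against an adjusted p of 0.481 with an estimated correlation. With arrays centred on their medians the list's median was -0.20 (camera adjusted p 0.0302).

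Markers of other lineages moved in both directions, and the ectoderm, trophectoderm and mesoderm lists were not called (camera adjusted p values of 0.993, 0.0661 and 0.622). Among 15 ectoderm and neural genes, 3 were called higher and 3 lower. Fgf5, a growth factor of the primed epiblast, was 6.68-fold lower and the POU factor Pou3f1 (Oct6) 3.66-fold lower, while the eye and neural factor Pax6 was 3.81-fold higher and Map2, a microtubule-associated protein of neurons on chromosome 1, 2.96-fold higher. Of 13 trophectoderm genes, 1 was higher and 6 lower at the adjusted p alone, and 0 were called higher and 2 lower. These were Krt18, a simple epithelial keratin (from 5244 ± 340 to 1896 ± 95.5; SD, n = 3), and the low-intensity transcript of Cdx2 (2.09-fold lower with values under 32 raised to 32). Of 10 mesoderm genes, the homeobox gene Evx1 was higher by 1.33 and the VEGF receptor Flt1 was at -2.56 (4.23-fold lower with the floor). Flt1 was at -0.85 without heterozygous replicate 1, at -1.15 without replicate 2 and at -0.69 without replicate 3, settings that choose its brightest probe set anew. The trophectoderm list was called lower in 5 alternatives with camera, at adjusted p values from 0.0302 to 0.0483, among them the fit without null replicate 3.

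Germline genes and markers of the 2-cell state also changed without a call of either list (camera adjusted p values of 0.129 and 0.0795). Of 20 germline genes, 7 were higher and 3 lower. Sohlh2, a transcription factor of early germ cell differentiation, rose from 335 ± 26.2 to 1577 ± 76.3 (SD, n = 3), 4.71-fold. The X-linked homeobox gene Rhox6 rose 4.14-fold and Hormad1, a protein of meiotic chromosome axes, 3.65-fold. Asz1 rose from 5.44 ± 5.67 to 46.8 ± 16.4, a fold of 1.41 with values under 32 raised to 32, which is short of the threshold. Sycp1 and Sycp3, components of the synaptonemal complex, fell (-1.74 and -1.38), and so did Taf7l (-1.30). Of 4 genes of the 2-cell state, Usp17la and Arg2 were lower, by folds of 4.24 and 3.55, with Arg2 at 34.1 ± 15.4 in null cells, near the floor of 32. The 2-cell list was called with eBayes without an intensity trend (camera adjusted p 0.0385), with arrays centred on their medians (0.0302) and without null replicate 1 (0.0478).

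Some signalling, stress and cell death genes changed. Smad6, an inhibitor of BMP signalling, rose 2.74-fold and Tgfb1 fell 3.55-fold, the only calls among 18 genes of Nodal, TGF-beta and BMP signalling. Among 18 p53 targets, Cdkn1a and Btg2 rose, and Ddit4, an inhibitor of mTORC1, Bbc3 (Puma), a promoter of apoptosis, and the kinase Plk2 fell by 1.58, 1.28 and 1.11 on the log2 scale. Plk2 was at -0.96 with arrays centred on their medians. Casp2 and Bbc3 were the only calls among 18 apoptosis regulators. Of 16 stress genes, 0 were called higher and 3 lower, against 2 higher and 7 lower at the adjusted p alone. Sqstm1 rose by 0.9965, just short of the threshold of size. The immediate early gene Egr1 fell from 3172 ± 245 to 954 ± 42.9 (SD, n = 3), Ier3 from 666 ± 5.70 to 251 ± 2.82 and the heat shock gene Hspa1b from 932 ± 170 to 465 ± 104. Hspa1b was not called without heterozygous replicate 1 (-0.91), heterozygous replicate 2 (-0.95) or null replicate 2 (-0.84), with arrays centred on their medians (-0.86), as a mean over probe sets (-0.99) or with log2(value + 16) (-0.98). None of these lists was called, with camera adjusted p values from 0.197 to 0.622; the p53 list was called lower with means over probe sets (0.0451).

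Of 21 small RNA pathway genes, 2 were called higher and 0 lower, against 6 higher and 5 lower at the adjusted p alone. The small RNA, polycomb and sterol lists were not called (camera adjusted p of 0.622 each). The RNA helicase Mov10 rose from 985 ± 71.0 to 2969 ± 144 (SD, n = 3), and Ago1, an Argonaute protein that binds microRNAs, rose 2.16-fold. Mov10 was at 0.75 as a mean over its probe sets. Of 19 polycomb genes, 3 were called higher and 1 lower, against 7 higher and 5 lower at the adjusted p alone. Bmi1, a part of the PRC1 complex, rose 2.82-fold, the methyltransferase Ezh1 2.78-fold and the chromobox gene Cbx8 3.47-fold, while Cbx7 fell 2.34-fold. Ezh1 and Cbx8 are on chromosome 11, whose tested genes had a median of 0.29. Ezh1 was at 0.70 without probe sets that share sequence, a setting that replaces its _a_at probe set by another. Of 15 sterol synthesis genes, 0 were called; Dhcr7 and Lss, both enzymes of the pathway, differed by -0.40 each, and Lss was at 0.45 without probe sets that share sequence.

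Some markers of feeder fibroblasts and of the sex chromosomes also differed. Of 14 fibroblast genes, 1 was called higher and 4 lower. Tagln, an actin-binding protein, fell from 4170 ± 187 to 1054 ± 87.4 (SD, n = 3), Col1a1 from 70.0 ± 28.0 to 6.62 ± 1.91 and S100a4 from 55.9 ± 9.44 to 15.0 ± 8.08, while the matrix proteoglycan Dcn rose from 31.0 ± 23.8 to 263 ± 56.6. With values under 32 raised to 32, Col1a1 was 2.05-fold lower and Dcn 6.61-fold higher. S100a4 was at -0.79, short of the threshold, with values under 32 raised to 32. Xist, the RNA that silences an X chromosome, fell from 336 ± 29.6 to 122 ± 2.20. The Y-linked gene Eif2s3y read 1621 ± 180 and 2723 ± 338, a fold of 1.68 with a limma adjusted p of 0.000119, while Uty, the other Y-linked gene measured, read 233 ± 8.67 and 183 ± 18.1 (adjusted p 0.0653). Neither list was called (camera adjusted p values of 0.129 and 0.622), but the fibroblast list was called lower with eBayes without an intensity trend (0.0354) and with arrays centred on their medians (0.042).

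**Figure D2:**
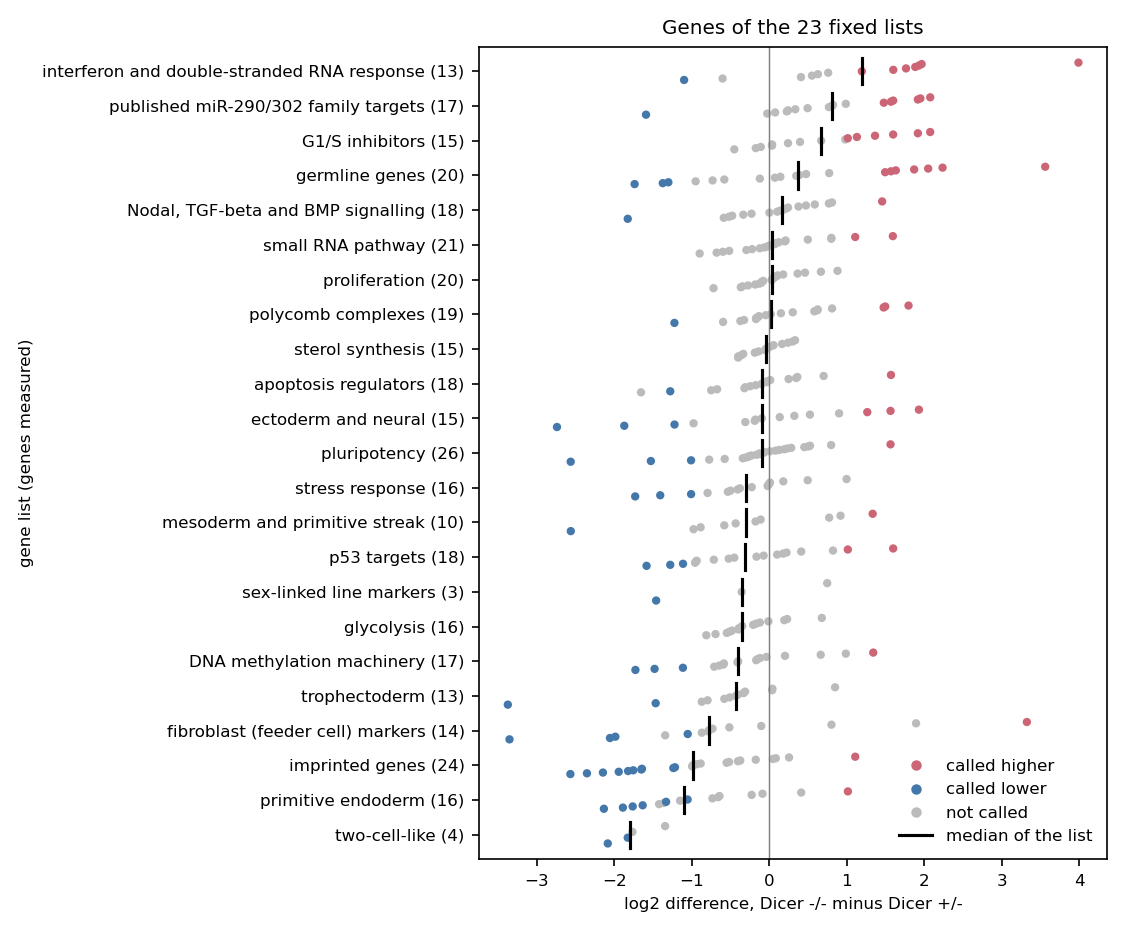
Log2 difference, null minus heterozygous, of each measured gene of the 23 lists (horizontal axis), with red points called higher, blue points called lower, grey points not called and a black bar at each list's median. The imprinted genes lie around a median of -0.99, the published miR-290 targets around 0.81 and the interferon genes around 1.19.

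Genes of whole chromosomes also differed between the lines. The 724 tested genes of chromosome 1 had a median log2 difference of 0.31 and the 1094 of chromosome 11 a median of 0.29, with 73.1% and 70.3% of them above 0. The medians were 0.34, 0.33 and 0.35 in the 3 null arrays for chromosome 1, and 0.29, 0.29 and 0.30 for chromosome 11. The median of chromosome 7 was -0.11, that of chromosome 15 -0.10 and that of X -0.15. Chromosomes 1 and 11 held 14.1% of the tested genes, 24.3% of the genes called higher and 7.36% of those called lower. Among the genes named above, Lgals3bp, Lpo, Cbx8, Ezh1, Col1a1 and Sparc are on chromosome 11, and Lrrn2, 1700019A02Rik, Lefty1, Lefty2, Prdm14, Btg2 and Map2 on chromosome 1. Without the genes of both chromosomes, 706 genes were higher and 742 lower, and 6 lists were called.

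**Figure D3:**
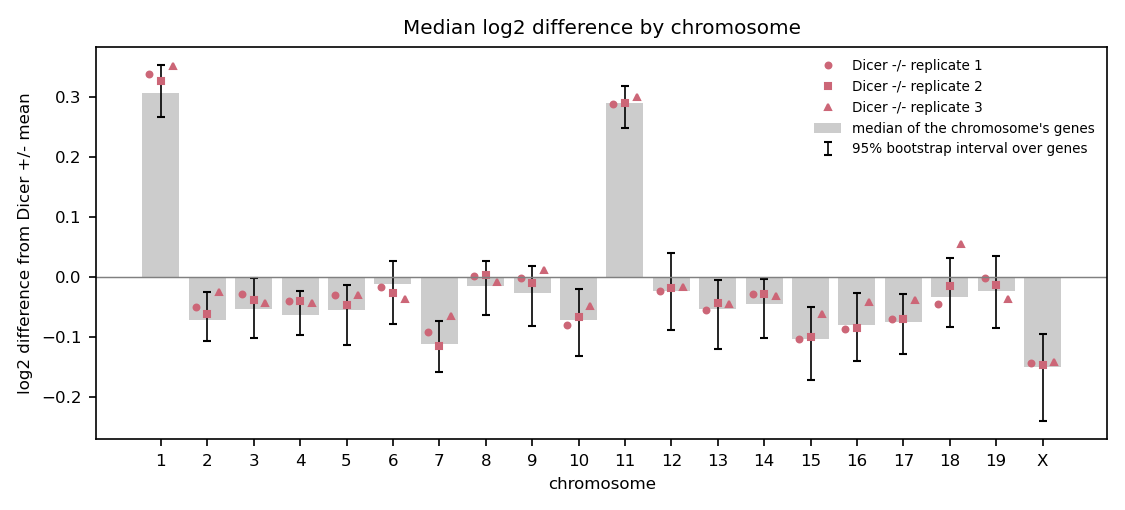
Median log2 difference from the heterozygous mean by chromosome, with grey bars for all 6 arrays, black 95% bootstrap intervals over genes, and red symbols for the 3 null arrays taken singly. Chromosomes 1 and 11 stand at 0.31 and 0.29, and the other chromosomes lie between -0.15 and -0.01.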

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

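The tests of RNA degradation, of a shift with expression level and of a few strong genes, and the position blocks and other splits of the chromosome medians, were chosen after the results were seen. Probe sets with no gene symbol or with several took part in no gene-level result, and 111 of 3168 such probe sets were called higher and 225 lower in null cells in the fit of all probe sets. Probe set 1419304_at fell from 873 ± 46.7 to 6.27 ± 4.10, and 1448057_at rose from 12.3 ± 10.6 to 357 ± 9.21 (SD, n = 3).

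The control probe sets of Actb, which read the 3′ and 5′ ends of the same transcript, lay farther apart in null cells. The 3′ minus 5′ log2 difference was 0.48 ± 0.06 in heterozygous and 0.81 ± 0.02 in null cells (SD, n = 3), 0.33 apart, with no overlap between arrays. The two-sided exact permutation p was 0.1, the smallest that 3 arrays against 3 can give. Unequal RNA degradation, which would widen the gap for all 4 control transcripts, may be set against the other 3. Their differences were 0.01 for Gapdh, 0.25 for Tfrc and -0.22 for Pcx, so 1 of the 4 widened by 0.3 or more, which argues against degradation as the source of the 1736 calls. Of the 10 splits of the arrays into 3 and 3, the real one, and thus 1 of them, gave as many calls. The highest of the others gave 0. Each of the others mixes the lines and so dilutes any difference between them, so their lack of calls decides nothing. With 10 splits no share under 0.05 can be reached.

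The shift of chromosomes 1 and 11 may reflect a copy number that differed between the lines. A difference of more than 0.2 from all genes had been set as the mark of this before the data were examined. Chromosome 1 stood 0.3208 above the median of all genes and chromosome 11 0.3043. Other splits of the arrays gave at most 0.1288 and 0.1158. Each of these mixes the lines and so dilutes any difference between them, which leaves this comparison unable to decide anything. Both medians stayed up after matching on mean expression (lower value 0.2963), which argues against a shift with expression level. Over genes that were not called, the lower value was 0.2246. A few strong genes could not have moved a median over so many genes, so that value decides nothing. The shares of genes above 0, 73.1% on chromosome 1 and 70.3% on chromosome 11, argue against a few strong genes. The position blocks, 8 per chromosome, had medians from 0.19 to 0.41 on chromosome 1 and 0.19 to 0.38 on chromosome 11, and medians over 51 neighbouring genes ran from 0.14 to 0.55 on chromosome 1 and from -0.04 to 0.6095 on chromosome 11, and whether the shift was even along them was not tested. An extra copy in every cell would give 0.58 if expression followed copy number. Whether a line gained or lost copies, in all or some cells, and whether Dicer played a part, stays open with 1 line per genotype.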

How the results depend on the processing

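The 1736 calls moved by less than 1.5 times under most settings, and the lack of detection calls leaves genes of low intensity the least certain. Apart from the adjusted p alone, the planned gene-level alternatives that kept the filter gave 1459 to 1859 called genes, and leaving out 1 array gave 1569 to 1693, with 848 to 956 higher and 629 to 845 lower and 6 to 7 called lists. A log2 filter of 7, which tests fewer genes, gave 1285 called genes, 525 of them lower, and 3 called lists. Testing every probe set gave 3262 calls (1585 higher, 1677 lower), and the adjusted p alone gave 6305 (3162 and 3143). Leaving out probe sets that share sequence gave 3 called lists. Camera with estimated correlations called 0 lists, with 4 at an unadjusted p under 0.05, and fry called 17. The settings chosen after seeing the data, other log scales, centring on the tested genes and leaving out chromosomes 1 and 11, gave 1448 to 1748 calls. With the replicate number as a block, 1746 genes (937 higher, 809 lower) and 7 lists were called, the DNA methylation machinery being the one gained. Same-numbered arrays were not taken as paired, since the study's design names no pairing. Their deviations from the means of their lines correlated at 0.03, 0.03 and 0.08. Each array correlated best with its own number. Deviations from a mean of 3 arrays sum to 0, so some arrays had to match with a positive value. These small values therefore leave pairing open.

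Values that turned sign were not called, and the cause was not tested. Dicer1 was at -0.0091 with probe set 1460571_at. With arrays centred on their medians, Pou5f1 was at 0.028 and the list medians were 0.057 (pluripotency), 0.061 (apoptosis regulators), 0.057 (ectoderm and neural) and 0.11 (sterol synthesis). Ectoderm and neural genes were at 0.018 with no filter or a filter of 3 and at 0.0071 with log2(value + 16). Sex-linked markers were at 0.20, 0.20 and 0.11 in these settings, at 0.22 as means over probe sets and at 0.77 without probe sets that share sequence, where Lss was at 0.45. Means over probe sets gave -0.18 (small RNA pathway), -0.10 (proliferation) and -0.13 (polycomb), and leaving out shared sequence gave -0.024 and -0.10 for the small RNA pathway and proliferation. Polycomb genes were at -0.014 with a filter of 7. In the order small RNA pathway, proliferation and polycomb, centring on the tested genes gave -0.010, -0.012 and -0.029, and leaving out chromosomes 1 and 11 gave -0.014, -0.088 and -0.13. With 1 array left out, the medians were -0.0035 to 0.066 (small RNA pathway), -0.14 to 0.012 (ectoderm and neural) and -0.0064 to 0.038 (polycomb). Of 94 named genes, 73 kept direction and side of the threshold in every setting in which they were tested. Genes that fell below the filter in a setting were not tested there. Leaving out any null array removed Lrrn2 and Ifit1 among others, and leaving out any heterozygous array removed Calb2 and Slc39a8 among others. With a log2 filter of 7, 76 of the named genes were tested. The planned test of microRNA seed matches was not run.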

Other observations

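The tests of imprint methylation and the values without chromosomes 1 and 11 were chosen after the results were seen. Interferon genes outside the fixed list were higher too. A list of 30 measured genes, written after the fixed list was seen to be higher and sharing Mov10 with the small RNA list, had 17 genes called higher and 0 lower, a median of 1.2933 and a camera p of 0.0064 with an estimated correlation. Ifi35, an interferon-induced protein, rose from 675 to 5572, the proapoptotic factor Xaf1, which like Ifi35 lies on chromosome 11, from 508 to 3368 and the immunoproteasome subunit Psmb8 from 118 to 785. The peptide-loading factor Tapbp rose from 1533 to 3901, while B2m, the light chain of MHC class I, read 1515 and 1435 (means, n = 3). With the genes of chromosomes 1 and 11 left out, 24 genes had a median of 1.13, 12 called higher and a camera p of 0.00551 with an estimated correlation. These values are consistent with a broad interferon response in the null line as a hypothesis; its trigger was not tested.

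Targets of ERK signalling were lower in part. After Dusp4, an ERK phosphatase, was seen to fall from 748 ± 60.6 to 82.4 ± 30.3 (SD, n = 3), a separate list of 17 measured targets was tested. Of these, 0 were called higher and 5 lower, among them the feedback inhibitors Spry1 (-2.12) and Spry4 (-1.55), the ETS factor Etv4 (-1.61) and Myc (-1.24), while Etv5 read 0.08 and Spred2 0.52. The median was -0.4831 and the camera p 0.0777 with an estimated correlation, so a lower output of the pathway as a group, a candidate explanation for the fall of Fgf5 and Egr1, was neither shown nor excluded.

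The fall of imprinted genes may have several sources. Loss of methylation at an imprinting control region would move the maternally and paternally expressed genes of its domain apart. The maternal and paternal medians were -0.97 and -0.99, the higher of them -0.9676. They pool genes of different domains and so cannot decide this. Meg3 and Rian (-1.82 and -2.35) fell together with Dlk1 (-1.64), the paternally expressed gene of their domain, which argues against it as the whole cause there. A lower copy number of their segments would lower the neighbours too. The median of 52 genes within 5 places of the 10 imprinted genes called lower was -0.0392. As a set these neighbours were not lower. They lie on chromosomes 2, 6, 7 and 12, so the pooled median cannot decide about any 1 segment. Of 8 maternally expressed genes, 3 were called lower and 0 higher, and of 15 paternally expressed genes, 7 were called lower and 1, Plagl1, higher. The primitive endoderm and fibroblast lists also had medians below 0, at -1.10 and -0.78. An effect of Dicer loss, a difference between the lines that arose in culture and a different share of other cell types stay open.

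Of the collagen genes Col1a1, Col1a2 and Col3a1 and of Sparc, 1 was lower by at least 1 on the log2 scale, so the test set for carried-over feeder fibroblasts was undecided; Col1a2 and Col3a1 differed by -0.79 and -0.87 at low intensity, and Sparc by 1.01. Called genes lay next to each other more often than shuffled orders gave. Of 12861 adjacent pairs of tested genes, 1.485% were called in the same direction, against 0.754% to 1.06% in shuffled orders, and without chromosomes 1 and 11 the values were 1.37% against 0.688% to 1.005%. The probe sets of 6 genes (Dtl, Gabbr1, Kat7, Mtm1, Nono and Zwint) were called in both directions.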
